A study of Homo sapiens with 12 samples.

How the data were processed

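The samples were peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of blood) of 1 healthy donor, cultured for 6 h with 20% serum. The sera came from 6 subjects with low and 6 subjects with high levels of IL-1ra, the interleukin-1 receptor antagonist, and 1 array was run per serum. Sample titles divide the sera of each level into 2 classes of 3, written AbN and T1D, which the labels do not spell out. The 12 arrays therefore fell into 4 groups of 3. Replicate numbers were given in accession order and only name an array.

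Per the labels' protocols, 200 ng of total RNA was extracted with a column kit, converted into biotin-labelled cRNA and hybridised to Illumina HumanRef-8 version 3.0 beadchips, arrays on which each probe is carried by many beads. Per the file headers, the authors exported the raw table from BeadStudio 3.2.7 without normalization. Its probe signals are deposited as intensity on a linear scale, the mean over the beads of a probe. The spread over the beads is deposited beside it as an intensity. A bead count per probe is deposited as well. The detection column is deposited as a fraction, 1 minus the detection p-value against the negative control beads. A second table holds the authors' processed values, deposited on a log2 scale. How these were made is not given in the sources used here. It was used only as an alternative. The position of each array on a beadchip is not given in the sources used here.

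Probes were named from the platform annotation, and symbols were updated through Entrez identifiers. Of 24526 probes, 21834 had 1 gene symbol, none had several and 2692 had no symbol in the table used. The symbols of 21813 probes were found in the updated table. Probes of XIST and of Y-chromosome genes, 67 in number, were left out. No column of per-sample values was left unused.

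Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits the background on negative controls inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p under 0.01 on at least 3 arrays were kept, 15144 in all. The probe of highest mean level stood for a gene, which left 11406 genes. Levels in the text are these normalized log2 values.

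Each gene was fitted with limma on the 4 group means over all 12 arrays, and 5 contrasts were taken: high minus low IL-1ra sera, T1D minus AbN sera, high minus low within each class, and the difference between the classes in high minus low. Moderated statistics came from eBayes, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. All tests were two-sided. Gene lists, 39 in number, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation, fry, and exact permutation of the list scores were run beside it. The list score of an array is the mean deviation of the list's genes from their means over the 12 arrays. Permutations of the labels within strata gave 400 arrangements and a smallest p of 0.005, and those within 1 class gave 20 and a smallest p of 0.1. A count adjusted over the list alone uses Benjamini-Hochberg within that list.

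The genes named were fixed by rule. For the first 2 contrasts the rule took up to 12 genes per direction past the threshold, filled to 6 with the genes of smallest unadjusted p where fewer passed. For the other contrasts it took up to 6, filled to 3. Up to 4 members of smallest p per list and 9 genes of the IL-1 axis were added. The groups, contrasts, lists, naming rule and most of the other settings tried were fixed before the data were examined. These settings changed the background correction, the scaling, the source of the values, the filter, the probes per gene, array weights, the variance model, the arrays in the fit and the list test. Array brightness as a covariate, and fits without or blocked for arrays of low neutrophil or hemoglobin signal, were added after the data had been seen.

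The fit was tested on simulated data with 200 changed genes among 11406, in which genes varied independently of each other. For high minus low sera it recovered 24 of 80 genes changed by 0.5 on the log2 scale, 47 of 55 changed by 1 and 65 of 65 changed by 2, with 5 false calls. For T1D minus AbN it recovered 18 of 62, 53 of 63 and 74 of 75. Within AbN sera it recovered 5 of 58, 37 of 69 and 66 of 73, and within T1D sera 8 of 66, 34 of 58 and 75 of 76. For the difference between the classes it recovered 1 of 59, 15 of 69 and 56 of 72. A simulated list of 35 genes shifted by 0.3 was called with the preset correlation, with 0 other lists called. This was 1 draw with a correlation of 0 between genes. As real genes are correlated, these counts hold for the simulated setting only. Where a group had no array on which a gene was detected, a fold was given only as a bound, with the undetected arrays set to at least the lowest detected signal of the same array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.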

Results

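The data are the gene expression profiles of PBMC of 1 healthy donor after 6 h with 20% serum of 12 subjects, 6 of low and 6 of high IL-1ra. IL-1ra, encoded by IL1RN, occupies the interleukin-1 receptor without signalling. Sera of the classes AbN and T1D were represented by 3 arrays at each IL-1ra level. Median raw signals lay between 154.1 and 216.6 per array, and 13611 to 14691 of the 24526 probes were detected. The median number of beads per probe was 37 to 40. Because the responder cells came from 1 donor, all p-values measure the spread between sera and cultures on these cells, and the number of arrays limits the precision. Arrays of low IL-1ra sera were brighter on average, with a mean median raw signal of 189.1 ± 21.6 (SD, n = 6) against 164.7 ± 6.66 (SD, n = 6) with high IL-1ra sera. The dimmest array of all, T1D low replicate 3 (154.1), was also of the low level.

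The 12 arrays differed in transcripts of granulocytes and red cells. On 4 arrays, 1 of each group, the neutrophil marker list scored between −0.55 and −0.52, against 0.11 to 0.39 on the other 8. The list of 11 erythroid genes scored between −2.35 and −0.44 on the same 4 arrays, against 0.12 to 1.05 on the other 8. Within the 4, hemoglobin beta (HBB) read 8.40 on AbN low replicate 2 and 8.26 on T1D low replicate 1, and 13.84 or more on each other array of the 12. The labels name no batch, and these 4 arrays were picked out by their neutrophil score after the data had been seen. As each group holds 1 of the 4 arrays, differences between groups are given over all arrays, and for several lists also within the 8 and within the 4.

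**Figure D1:**
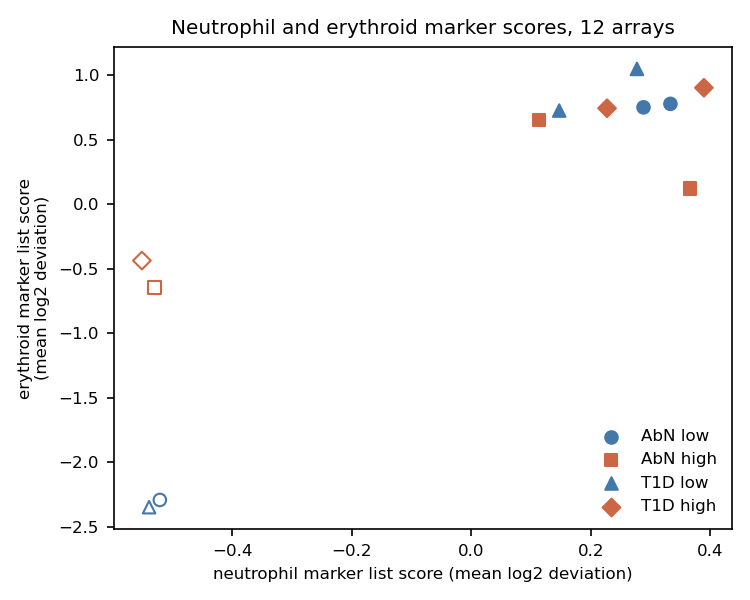
Neutrophil marker list score (horizontal) against erythroid marker list score (vertical), both as mean log2 deviation from the mean of all arrays, for the 12 arrays; symbols give the group and open symbols the 4 arrays of lower neutrophil signal. The 4 open symbols lie between −0.55 and −0.52 on the horizontal axis, and the other 8 between 0.11 and 0.39.

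The first comparison asks how cells responded to sera of high against low IL-1ra subjects. Genes of the interferon response had lower signal with high IL-1ra sera: the 33 measured genes of the type I interferon list were lower by a mean of 1.14 ± 0.39 (SE) on the log2 scale, with 33 of 33 members lower. Genes induced by IL-1 and NF-kB had higher signal, by a mean of 0.50 ± 0.19 (SE) over 35 genes, 32 of them higher. Antigen presentation genes were lower, by 0.41 ± 0.12 (SE) for MHC class II and 0.25 ± 0.11 (SE) for MHC class I. IL6 was 4.45 times as high, CXCL2 2.76 times and the cyclooxygenase gene PTGS2 2.08 times, while the antiviral enzyme gene OAS1 was at 0.294 times and the chemokine gene CXCL10 at 0.219 times its level with low IL-1ra sera. IL6 read up to 15.90 and CXCL10 up to 15.94 on single arrays, near the top of the scale, where a difference can be compressed. None of these single genes passed the threshold over all genes, and camera with an estimated correlation called 0 of the lists (lowest adjusted p = 0.385).

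By limma, 0 of 11406 genes passed an adjusted p of 0.05, and the lowest adjusted p was 0.169, shared by 32 genes. At an unadjusted p under 0.05 there were 1186 genes, 520 higher and 666 lower, where chance alone gives 570. The 6 genes of smallest p in each direction did not pass. Those higher with high IL-1ra sera were TMEM65, a mitochondrial inner membrane protein gene (0.90 ± 0.16 SE), ANTXR2, an anthrax toxin receptor gene (0.69 ± 0.12), the stress kinase gene MAP3K20 (0.88 ± 0.16), ANP32A (0.71 ± 0.13), its pseudogene ANP32AP1 (0.51 ± 0.10) and the microtubule-associated MAP7 (0.54 ± 0.11). The probes of ANP32A and ANP32AP1 may bind the same transcripts, so their values are not separate. Those lower were the cohesin subunit gene REC8 (−0.68 ± 0.10), the galectin gene LGALS9 (−1.43 ± 0.23), SCIMP (−1.05 ± 0.17), the phagocytic receptor gene MERTK (−1.17 ± 0.22), UNC93B1, which carries endosomal Toll-like receptors (−0.79 ± 0.15), and CD1E, a lipid antigen presentation gene (−1.28 ± 0.24, and −0.37 on a dimmer probe). In each of TMEM65, ANTXR2, MAP3K20, ANP32A and MAP7 all 6 arrays of high IL-1ra sera lay above all 6 of low IL-1ra sera, and in REC8, LGALS9, SCIMP and UNC93B1 all 6 lay below. As these genes were picked by their small p-values in the same data, this separation adds no support. Without AbN low replicate 2 limma called 34 genes, all lower, and without both arrays of low hemoglobin signal 35, all lower. Of these, 30 were called in both fits, and 13 of the 30 belong to the type I interferon list. Both fits leave out AbN low replicate 2, so their overlap is not separate support. The type I score of that array was −0.732, against 0.166 to 1.41 on the other low IL-1ra arrays. Leaving it out therefore favours lower calls in this list. The 34 included MX1 (−1.38), ISG15 (−1.94), IFI6 (−1.22) and APOBEC3A (−3.98), named after their values were seen. LGALS9 alone was called without AbN high replicate 3 (−1.65, adjusted p = 0.00514) and with array weights (−1.65, adjusted p = 0.0461).

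Of the 39 gene lists, camera with its preset correlation called 10, 3 higher and 7 lower, and with an estimated correlation it called 0, with 5 at an unadjusted p under 0.05. Fry called 0 lists in 1 direction, with 7 at an unadjusted p under 0.05, and 15 lists as changed in either direction. Exact permutation of the list scores within the classes gave 10 lists an unadjusted p under 0.05 and 0 after adjustment (lowest p = 0.01, adjusted p = 0.146). Among the called lists it gave MHC class II an exact p of 0.015, MHC class I and TGF-beta 0.025, IL-1 and NF-kB 0.03, CD16 monocytes 0.05, Toll-like receptors 0.1, CD8 and NK cells 0.22 and the stress response 0.235, with adjusted p-values of 0.146 to 0.436. On simulated data in which the type I interferon list was not shifted and kept its own correlation of 0.854, it had an unadjusted p under 0.05 in 67 of 100 draws with the preset correlation and in 3 with the estimated correlation. As genes of a list can move together, counts of members higher, lower or past the threshold within any list are not separate support.

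In the type I interferon list, genes by which cells answer interferon alpha and beta, camera gave an adjusted p of 2.40e-26 with the preset correlation and an adjusted p of 0.385 with the estimated correlation. Adjusted over the list alone, 30 of its 33 genes passed, all lower, against 0 over all genes. Examples were the transcription factor gene IRF7 (−0.98 ± 0.19), OAS1 (−1.76 ± 0.41), SAMD9L (−1.27 ± 0.32) and IFIT1 (−1.73 ± 0.44). A dimmer second probe of IRF7 read −0.06. The list score was lower in 6 of 6 arrays of high IL-1ra sera than the mean of the low ones, and in 2 of the 6 lower than every low one. Among the 8 arrays of higher neutrophil signal the difference was −1.56 ± 0.33 (SE), and among the other 4 it was −0.31. The exact permutation p of the score was 0.015 (adjusted p = 0.146).

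The interferon-gamma list, which shares no gene with the type I list, differed by −1.08 ± 0.48 (SE), with 20 of 21 members lower. Camera gave an adjusted p of 1.62e-10, and an adjusted p of 0.467 with the estimated correlation. The threshold was passed by 9 genes adjusted over the list alone, all lower, against 0 over all genes. They included the Fc receptor gene FCGR1A (−2.42 ± 0.61), the complement inhibitor gene SERPING1 (−1.95 ± 0.50), the aminopeptidase gene LAP3 (−1.15 ± 0.32) and CXCL10 (−2.19 ± 0.64). A dimmer second probe of SERPING1 read 0.15. Within the 8 arrays the list differed by −1.13 ± 0.68 (SE), a wider error than over all 12. Within the 4 it differed by −0.98, and without AbN low replicate 3 by −0.72. The exact permutation p of the score was 0.07 (adjusted p = 0.195). By class, the list differed by −0.42 ± 0.68 (SE) within AbN sera and by −1.74 ± 0.68 (SE) within T1D sera. The AbN difference rests on AbN low replicate 3, which scored 1.506. AbN low replicates 1 and 2 scored −0.622 and −0.730, within or near the −0.747 to 0.266 of the AbN high arrays.

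In the IL-1 and NF-kB list, camera gave an adjusted p of 1.62e-10, and an adjusted p of 0.385 with the estimated correlation. Of its 35 genes, 8 passed adjusted over the list alone, all higher, against 0 over all genes. Examples were IL1A, which encodes interleukin-1 alpha (0.79 ± 0.16), the chemokine genes CCL20 (0.88 ± 0.20) and CXCL2 (1.47 ± 0.37), and PTGS2 (1.06 ± 0.27). All 6 arrays of high IL-1ra sera scored above the mean of the low ones, and 4 scored above every one of them. The list differed by 0.66 ± 0.20 (SE) within the 8 arrays and by 0.17 within the 4. Of the other IL-1 axis genes, IL6 differed by 2.15 ± 0.64 (adjusted p = 0.263), IL1RN by 0.39 ± 0.19, IL1R1 by 0.52 ± 0.37 and TNF by 0.23 ± 0.27. The IL1RN probe lay near the top of the scale, and 2 dimmer probes of IL1RN read 0.74 and 0.53. Without T1D low replicate 2 the IL1R1 difference was 0.11 and that of IL1RN 0.22, and without T1D low replicate 1 that of IL1R1 was 0.78. The TNF difference was 0.08 without AbN high replicate 1 and 0.42 without AbN low replicate 3. IL6 differed by 2.87 within the 8 arrays and by 0.73 within the 4. Over both classes it differed by 1.595 without AbN high replicate 1 and by 2.678 without AbN high replicate 2. IL1B (0.00 ± 0.08) and CXCL8 (0.03 ± 0.08) were among the 19 brightest probes on every array, where the scanner range leaves little room for a difference. IL1R2 was not measured.

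**Figure D2:**
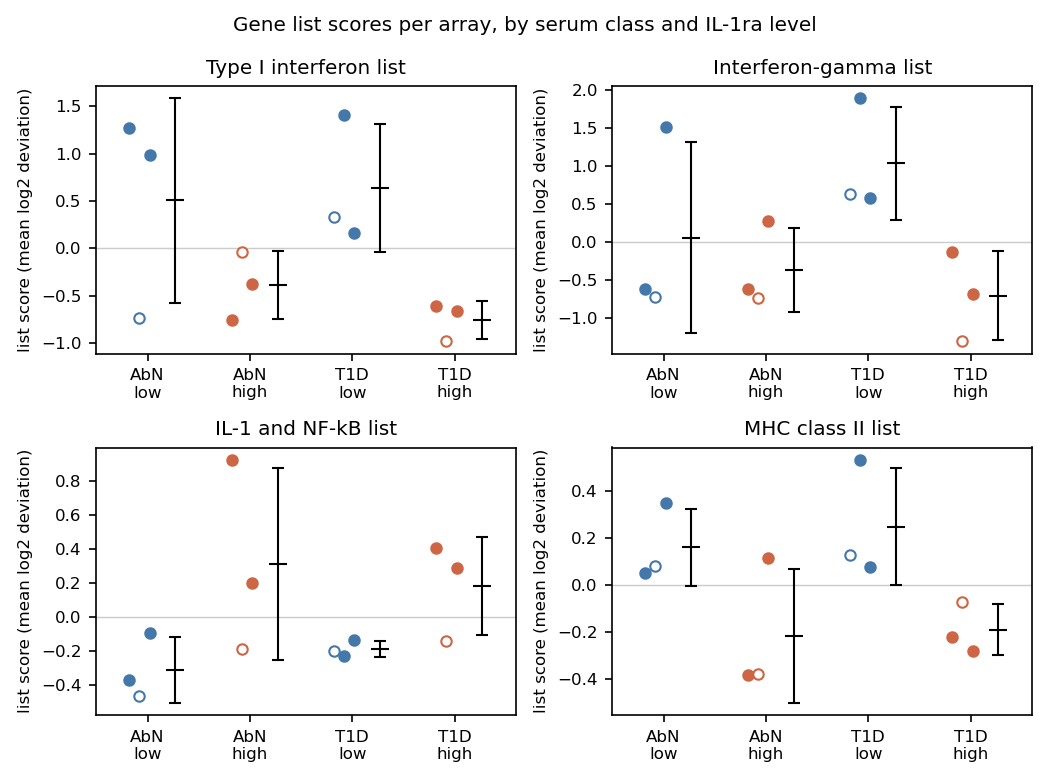
List score per array (mean log2 deviation of the list's genes) for 4 gene lists, by serum class and IL-1ra level; points are arrays, open points the 4 arrays of lower neutrophil signal, and bars the mean ± SD of 3 arrays. In the type I interferon list the arrays of high IL-1ra sera lie between −0.98 and −0.04 and those of low IL-1ra sera between −0.73 and 1.41, where the lowest low array is AbN low replicate 2.

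The MHC class II list had 16 of 17 members lower (camera adjusted p = 9.85e-09, and adjusted p = 0.385 with the estimated correlation). Adjusted over the list alone, 10 passed, all lower, among them the peptide loading gene HLA-DMA (−0.64 ± 0.15), the protease gene CTSS (−0.39 ± 0.11) and the regulator gene CIITA (−1.09 ± 0.33). It differed by −0.44 ± 0.18 (SE) within the 8 arrays and by −0.33 within the 4. In the MHC class I and immunoproteasome list 13 of 16 members were lower (adjusted p = 0.00727, and adjusted p = 0.467 with the estimated correlation). The immunoproteasome gene PSMB8 (−0.74 ± 0.17) was the 1 gene that passed adjusted over the list alone, and the peptide transporter gene TAP1 differed by −0.65 ± 0.23. This list was not called without T1D low replicate 2 (−0.20, adjusted p = 0.130). The Toll-like receptor and inflammasome list differed by −0.24 ± 0.13, with 18 of 25 members lower (adjusted p = 0.00974, and adjusted p = 0.467 with the estimated correlation). Adjusted over the list alone, 3 passed: the endotoxin co-receptor gene CD14 (−0.33 ± 0.09), NOD1 (−0.58 ± 0.16) and the pore-forming GSDMD (−0.49 ± 0.14). It was not called without AbN low replicate 3 (−0.16) or T1D low replicate 2 (−0.16).

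Markers of 2 cell types were called lower as lists. The CD16 monocyte list differed by −0.24 ± 0.11, with 9 of 12 members lower (adjusted p = 0.0204, and adjusted p = 0.467 with the estimated correlation). Adjusted over the list alone, 3 passed: VMO1 (−0.82 ± 0.20), the growth factor receptor gene CSF1R (−0.61 ± 0.17) and the chemokine receptor gene CX3CR1 (−0.78 ± 0.21). It was not called without AbN low replicate 1 (−0.18), AbN high replicate 2 (−0.21), T1D low replicate 2 (−0.21) or T1D high replicate 1 (−0.24). The CD8 and NK cell list differed by −0.14 ± 0.11, with 18 of 25 members lower (adjusted p = 0.0377, and adjusted p = 0.611 with the estimated correlation). CX3CR1 and the perforin gene PRF1 (−0.56 ± 0.13) passed adjusted over the list alone. Its call ended without AbN low replicate 1 (−0.15) or 3 (−0.10), AbN high replicate 2 (−0.12) or 3 (−0.14), T1D low replicate 2 (−0.10) or T1D high replicate 2 (−0.06). It also ended without the 4 arrays of lower neutrophil signal (−0.11), with array weights (−0.11) and with array brightness as a covariate (−0.17). The dendritic cell list, which was not called (adjusted p = 0.105, and adjusted p = 0.385 with the estimated correlation), differed by −0.25 ± 0.06, with 12 of 18 members lower. Its score lay below the mean of the low IL-1ra sera on 6 of 6 arrays, with an exact permutation p of 0.01 (adjusted p = 0.146). The general monocyte list, also not called, differed by −0.20 ± 0.10 (adjusted p = 0.0875).

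Higher as lists were the integrated stress and unfolded protein response, by 0.17 ± 0.14 with 17 of 22 members higher (adjusted p = 0.00813, and adjusted p = 0.467 with the estimated correlation), and the TGF-beta response, by 0.15 ± 0.06 with 9 of 14 members higher (adjusted p = 0.0323, and adjusted p = 0.385 with the estimated correlation). In the stress list 0 genes passed adjusted over the list alone, with the endoplasmic reticulum chaperone gene DNAJB9 at 0.47 ± 0.14. In the TGF-beta list 5 passed, 4 higher and 1 lower: examples were SMAD7, which dampens TGF-beta signalling (0.58 ± 0.13), ID2 (0.43 ± 0.13), TGIF1 (0.36 ± 0.12) and, lower, CX3CR1. The stress list differed by 0.08 and was not called without AbN low replicate 1, by 0.29 without AbN low replicate 3, and by 0.10 and was not called with array brightness as a covariate. The TGF-beta call ended without AbN high replicate 3 (0.16), T1D low replicate 2 (0.14) or 3 (0.13), T1D high replicate 2 (0.12) or the 4 arrays of lower neutrophil signal (0.12), and with array weights (0.13). Leaving out T1D low replicate 2 reduced the number of lists called from 10 to 5.

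**Figure D3:**
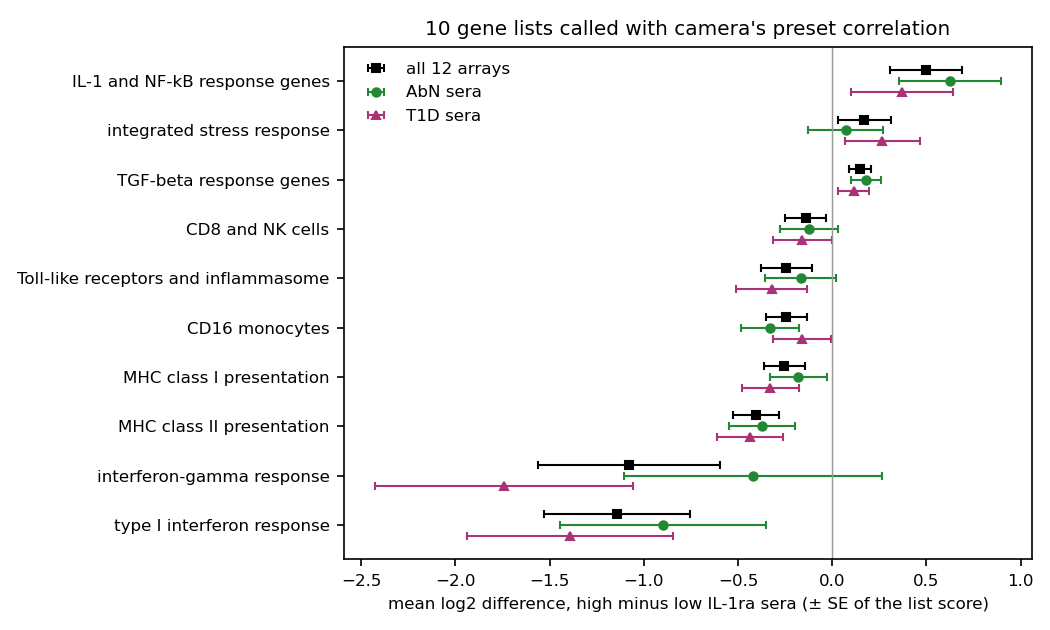
Mean log2 difference, high minus low IL-1ra sera, of the 10 lists called with camera's preset correlation, over all 12 arrays (squares), within AbN sera (circles) and within T1D sera (triangles); bars are the standard error of the list score. The type I interferon list lies at −1.14 over all arrays, −0.90 within AbN sera and −1.39 within T1D sera.

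**Figure D4:**
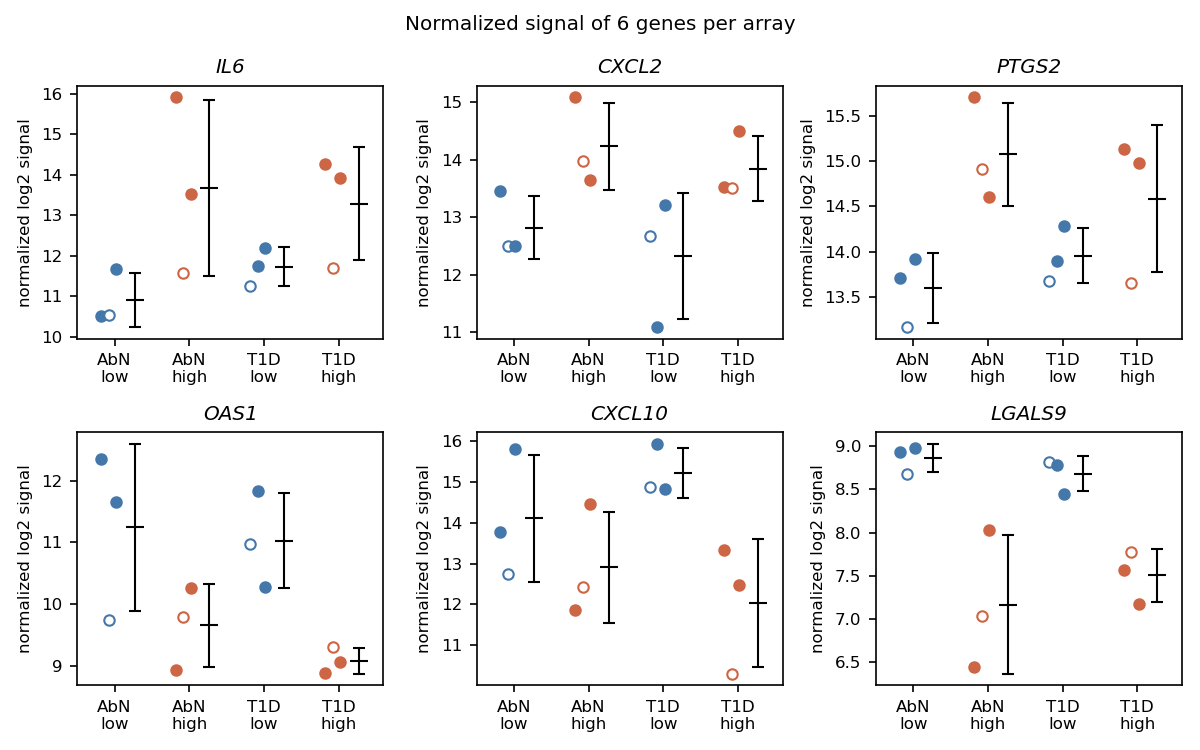
Normalized log2 signal of 6 genes per array, by serum class and IL-1ra level; points are arrays, open points the 4 arrays of lower neutrophil signal, and bars the mean ± SD of 3 arrays. LGALS9 lies between 6.45 and 8.03 with high IL-1ra sera and between 8.45 and 8.98 with low IL-1ra sera, while CXCL10 and OAS1 overlap between the levels.

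Within each serum class the same comparison was made on 3 against 3 arrays. With AbN sera, IL6 differed by 2.76 ± 0.91 and TNF by 0.91 ± 0.38, and with T1D sera IL6 differed by 1.55 ± 0.91 and TNF by −0.46 ± 0.38. Without AbN high replicate 1 the former IL6 difference was 1.64, and without T1D high replicate 1 the latter TNF difference was −0.145. With T1D sera IL6 differed by 1.07 without T1D high replicate 1 and by 2.35 without T1D high replicate 2. With AbN sera, ANP32A (0.96 ± 0.18), SLC35G1 (0.64 ± 0.13), REC8 (−0.80 ± 0.14) and LGALS9 (−1.70 ± 0.32) had the smallest p-values, and OLFML2B, detected on 3 arrays of low and 0 of high sera, was at least 1.98-fold lower with high sera. With T1D sera, the chemokine gene CCL8 (−4.65 ± 0.94), ANTXR2 (0.81 ± 0.17), NRIP3 (1.26 ± 0.27), FCRLB (1.35 ± 0.31) and SCIMP (−1.16 ± 0.25) had the smallest, and KPTN, detected on 2 arrays of low and 0 of high sera, was at least 1.06-fold lower. None passed: limma called 0 genes in either class, with lowest adjusted p-values of 0.444 for AbN and 0.688 for T1D sera. At an unadjusted p under 0.05 there were 663 genes for AbN and 631 for T1D sera, and the former count was 288 without AbN high replicate 1 and 1570 without AbN high replicate 3. In both classes, 43 genes were higher and 97 lower, where independent lists would share 6.40 and 12, and 3 went in opposite directions. These expected counts treat genes as independent. Genes that move together, as in the type I list, and the shared estimate of the spread can raise the shared counts. The excess is therefore no test of agreement between the classes. Without AbN high replicate 3, limma called LGALS9 within the AbN sera (−2.12, adjusted p = 0.0216).

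Camera called 4 lists within AbN sera: type I interferon (−0.90), MHC class II (−0.37) and CD16 monocytes (−0.33) lower, and IL-1 and NF-kB genes (0.62) higher. In the last, IL1A (0.95 ± 0.23) and PTGS2 (1.48 ± 0.39) passed adjusted over the list alone. With the estimated correlation 0 lists were called (lowest adjusted p = 0.616). The type I list differed by −1.69 within the AbN arrays of higher neutrophil signal and by 0.69 between the other 2. It differed by −0.52 without AbN low replicate 1 and by −1.52 without AbN low replicate 2. The IL-1 and NF-kB list differed by 0.32 without AbN high replicate 1, and the CD16 monocyte call ended without AbN low replicate 1 (−0.20) or AbN high replicate 2 (−0.26). Without AbN low replicate 2 the number of lists called was 13, without AbN low replicate 3 it was 12, and without AbN high replicate 2 or 3 it was 9 or 7. Within T1D sera 8 lists were called: type I interferon (−1.39), interferon-gamma (−1.74), MHC class II (−0.44), MHC class I (−0.33), Toll-like receptors (−0.32) and cell cycle genes (−0.29) lower, and IL-1 and NF-kB genes (0.37) and the stress response (0.27) higher. None held with the estimated correlation (lowest adjusted p = 0.385). There, 29 of 33 type I genes and 16 of 21 interferon-gamma genes passed adjusted over the list alone, all lower, with FCGR1A at −3.52 ± 0.86, CXCL10 at −3.18 ± 0.90 and IFIT1 at −2.18 ± 0.62. The type I list differed by −1.43 within the T1D arrays of higher neutrophil signal and by −1.32 between the other 2. Within T1D sera the MHC class I (−0.22) and Toll-like receptor (−0.16) calls ended without T1D low replicate 2, and the latter also with array weights (−0.25). The cell cycle call ended without the 4 arrays of lower neutrophil signal (−0.16) and with array brightness as a covariate (−0.20), and the stress call with brightness (0.19). Exact permutation within 1 class cannot go below p = 0.1.

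The difference between the classes in high minus low was tested directly. The interferon-gamma list differed more with T1D than with AbN sera, by −1.32 ± 0.97 (camera adjusted p = 1.05e-10, and adjusted p = 0.852 with the estimated correlation), with 21 of 21 members negative. It was −2.05 without AbN low replicate 3 and −0.89 without T1D low replicate 2. FCGR1A (−2.20 ± 1.21), GBP1 (−1.73 ± 0.91), GBP5 (−1.90 ± 1.02) and IRF1 (−1.15 ± 0.57) had its smallest p-values. Cell cycle genes differed by −0.42 ± 0.15, with 20 of 23 members negative (adjusted p = 4.71e-09, and adjusted p = 0.413 with the estimated correlation), among them TYMS (−0.73 ± 0.21), UBE2C (−0.95 ± 0.32) and BUB1 (−1.34 ± 0.49). High minus low in this list went in opposite directions, at 0.13 ± 0.11 within AbN sera and −0.29 ± 0.11 within T1D sera. The type I interferon list differed by −0.49 ± 0.77 (adjusted p = 7.78e-04, and adjusted p = 0.852 with the estimated correlation). Without AbN low replicate 2 (0.125) or with array weights (0.04) it was not called. Within the 8 arrays of higher neutrophil signal it differed by 0.27, and the preset correlation called it in the other direction (camera adjusted p = 0.0129). The call also ended without AbN high replicate 3 (−0.49), T1D low replicate 2 (−0.11) or the 2 arrays of low hemoglobin signal (−0.03). The type I difference was −0.875 without AbN low replicate 1 and −0.32 without AbN high replicate 2. By limma, 0 genes passed (lowest adjusted p = 0.9995), with 138 at an unadjusted p under 0.05, fewer than the 570 of chance. The genes of smallest p were OLFML2B, PNOC (1.92 ± 0.46), CHST7 (0.99 ± 0.28), TCF23, TYMS and SPIN2B (−0.94 ± 0.27). No size is given for OLFML2B and TCF23, which had groups with 0 arrays detected. The number of lists called moved from 3 to between 5 and 11 without AbN low replicate 1, 2 or 3, AbN high replicate 1 or 2, T1D low replicate 2, or T1D high replicate 1 or 2.

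The last comparison set T1D against AbN sera over both IL-1ra levels. The genes of smallest p did not pass: BHLHE41, a clock-related repressor gene (0.65 ± 0.18), SLC28A1 (0.43 ± 0.12), CLC, an eosinophil and basophil gene (0.55 ± 0.15), C1orf54 (0.33 ± 0.09), SDC4 (0.41 ± 0.12) and JAM2 (0.42 ± 0.12) were higher with T1D sera. SEPTIN10 (−0.62 ± 0.20), NAMPT, an NAD synthesis gene (−0.48 ± 0.16), and APBA2 (−0.42 ± 0.13) were lower (a dimmer probe of SEPTIN10 read −0.17), as was SREK1IP1 (−0.56 ± 0.15), which was detected on 1 of 6 T1D and 6 of 6 AbN arrays. MAPK8IP1 and ANKS4B were detected on 0 of 6 T1D and 3 of 6 AbN arrays, with no fold above the detection bound. Of the IL-1 axis, IL1RN differed by 0.19 ± 0.19 (0.07 and 0.36 without T1D low replicates 1 and 2), while its 2 dimmer probes read −0.29 and −0.12, IL1A by 0.03 ± 0.16 (−0.04 to 0.14 with 1 array left out), IL6 by 0.22 ± 0.64 (−0.31 and 0.78 without AbN high replicates 2 and 1) and IL1R1 by −0.74 ± 0.37, or −0.34 without T1D low replicate 2. By limma 0 genes passed (lowest adjusted p = 0.9998), with 220 at an unadjusted p under 0.05 against the 570 of chance. That count was 749 without the 4 arrays of lower neutrophil signal, and with 1 array left out it lay between 120 (T1D low replicate 3) and 512 (T1D low replicate 1). Camera called 2 lists. Interferon-gamma genes were higher with T1D sera by 0.32 ± 0.48, with 21 of 21 members higher, and cell cycle genes lower by 0.10 ± 0.08, with 18 of 23 lower. Both had an adjusted p of 0.0181, and an adjusted p of 0.941 with the estimated correlation, and no member passed adjusted over the list alone. CIITA (0.57 ± 0.33), GBP2 (0.34 ± 0.25) and IRF8 (0.25 ± 0.20) led the former, and MCM4 (−0.21 ± 0.13), AURKB (−0.30 ± 0.20) and UBE2C (−0.24 ± 0.16) the latter. Neither direction held on average at both IL-1ra levels. Among high IL-1ra sera the interferon-gamma score was on average lower with T1D (−1.314 to −0.134) than with AbN sera (−0.747 to 0.266). Among low IL-1ra sera the cell cycle score was on average higher with T1D (−0.024 to 0.268) than with AbN sera (−0.119 to 0.138). Over both levels, the 8 arrays of higher neutrophil signal gave 0.28 ± 0.68 (SE) for interferon-gamma and −0.05 ± 0.05 (SE) for cell cycle genes. Within the other 4 the differences were 0.39 and −0.19. In the fit on the 8 arrays both calls ended (camera adjusted p = 0.3175 and 0.3037). Each call ended without any of several single arrays: the interferon-gamma difference was 0.10 without T1D low replicate 2, 0.12 and 0.15 without AbN low replicates 2 and 1, 0.17 without T1D high replicate 1, and 0.22 and 0.25 without AbN high replicates 2 and 1. In the other direction it was 0.68 and remained called without AbN low replicate 3, and 0.48 without AbN high replicate 3. The cell cycle difference was −0.06 without AbN low replicate 2, −0.07 without AbN high replicate 2 or T1D low replicate 2, −0.08 without T1D high replicate 2, and −0.09 without AbN high replicate 1 or T1D low replicate 3.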

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

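Dixon's outlier test was run in 80 groups of 6 arrays, of which 5 passed the critical value of 0.625, where chance gives about 1 in 20 groups. The items tested were chosen after the results were seen. In AbN sera the MHC class I list score was highest on AbN low replicate 3, at 0.364 with the next at −0.027 (ratio 0.734). IL1R1 was lowest on T1D low replicate 2, at 9.04, both among low IL-1ra sera (next 11.13, ratio 0.676) and among T1D sera (next 11.17, ratio 0.797). HBB was lowest on AbN low replicate 2 among AbN sera (8.40, next 13.84, ratio 0.789) and on T1D low replicate 1 among T1D sera (8.26, next 14.28, ratio 0.847).

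High minus low differed between T1D and AbN sera in 3 lists by camera with its preset correlation: interferon-gamma (−1.321), cell cycle (−0.417) and type I interferon genes (−0.494). With the estimated correlation camera called 0 lists for this difference (lowest adjusted p = 0.413), with 1 at an unadjusted p under 0.05. The type I difference was 0.125 without AbN low replicate 2.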

How the results depend on the processing

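Each result was recomputed under other settings; array brightness as a covariate and the fits without or blocked for arrays of low hemoglobin or neutrophil signal were chosen after the results were seen. No paired analysis was possible because replicate numbers follow accession order and name no shared subject, and a block for the beadchip was not run because the files name no chips. For high against low sera limma called 0 genes, with 1186 at an unadjusted p under 0.05; it called 1 with array weights, 35 without the 2 arrays of low hemoglobin signal, and from 0 (without AbN low replicate 1) to 34 (without AbN low replicate 2) with 1 array left out. The lowest adjusted p ranged from 0.00514 (without AbN high replicate 3) to 0.698 (brightness as a covariate). Within AbN sera 0 genes were called, with 663 at an unadjusted p under 0.05, and 1 without AbN high replicate 3. That count of 663 was 288 without AbN high replicate 1 and 1570 without AbN high replicate 3. For T1D against AbN sera the 220 genes at an unadjusted p under 0.05 became 128, 443, 512, 353 and 120 without AbN low replicate 1, AbN high replicate 2 and T1D low replicates 1, 2 and 3. They became 749 without the 4 arrays of lower neutrophil signal, 424 without the 2 arrays of low hemoglobin signal, 429 with no filter on dim probes, 420 with array weights and 118 with brightness. Within AbN sera the 663 became 1297 with array weights and 432 without the 4 arrays, and within T1D sera the 631 became 963 with no filter. For the difference between the classes the 138 became 548, 331 and 213 without AbN high replicate 3, T1D low replicate 1 and T1D high replicate 3, 322 with no filter and 91 with probes detected on all 12 arrays. IL1B differed by −0.010 with array weights and between −0.010 (without T1D low replicate 2) and 0.012 (without AbN high replicate 1), and CXCL8 by −0.003 without the 4 arrays of lower neutrophil signal. For T1D against AbN sera IL1A differed by −0.055 without the 2 arrays, −0.039 without AbN low replicate 2 and 0.143 without T1D high replicate 2, and IL6 by −0.305 without AbN high replicate 2 and 0.778 without AbN high replicate 1. Camera with the estimated correlation and the one-direction test of fry called 0 lists in each of the 5 contrasts, while the test of fry in either direction called 15 for high against low sera and 0 for the others, and the preset correlation called 10, 2, 4, 8 and 3. With 1 array left out, high against low lists numbered 5 (without T1D low replicate 2) to 11 (without AbN low replicate 2). Lists for T1D against AbN numbered 4 with median scaling, 1 with probes detected on all 12 arrays, 1 with array weights, 0 in a 2-group fit, 0 without AbN high replicate 2 and 7 without AbN low replicate 3. They also numbered 1 without AbN low replicate 1, T1D low replicate 2 or T1D high replicate 1, 4 without AbN high replicate 3 or T1D high replicate 2, and 5 without T1D high replicate 3. Within AbN sera they numbered 7 with median scaling, 8 with no filter on dim probes, 8 with array weights, 13 without the 2 arrays, 11 without the 4 arrays, 8 with brightness, 4 without AbN low replicate 1, 13 and 12 without AbN low replicates 2 and 3, and 9 and 7 without AbN high replicates 2 and 3. For the difference between the classes they numbered 8 with array weights, 8 without the 4 arrays, 5, 6 and 11 without AbN low replicates 1, 2 and 3, 6, 8 and 2 without AbN high replicates 1, 2 and 3, 5 without T1D low replicate 2, and 11 and 6 without T1D high replicates 1 and 2. The list test alone leaves the differences as they are and changes the p-values. With the estimated correlation, high against low sera gave an adjusted p of 0.385 for IL-1 and NF-kB (0.496), type I interferon (−1.143), MHC class II (−0.405) and TGF-beta genes (0.146). It gave an adjusted p of 0.467 for interferon-gamma (−1.081), MHC class I (−0.254), Toll-like receptor (−0.244), stress (0.169) and CD16 monocyte genes (−0.244), and 0.611 for CD8 and NK genes (−0.141). Fry gave adjusted p-values from 0.114 to 0.472 for the same 10. The stress list differed by 0.095 with brightness, 0.083 without AbN low replicate 1 and 0.292 without AbN low replicate 3. The TGF-beta list differed by 0.132 with array weights, 0.117 without the 4 arrays, 0.115 without AbN low replicate 2 and 0.177 without T1D low replicate 1. The CD8 and NK list differed by −0.108 with array weights, −0.111 without the 4 arrays, −0.166 with brightness, −0.207 without T1D high replicate 1 and −0.061 without T1D high replicate 2. The CD16 monocyte list ranged from −0.310 (without AbN high replicate 3) to −0.183 (without AbN low replicate 1), MHC class I from −0.295 (without T1D low replicate 3) to −0.177 (without AbN low replicate 3), and Toll-like receptors from −0.324 (without AbN low replicate 2) to −0.162 (without T1D low replicate 2). For T1D against AbN sera the interferon-gamma list differed by 0.317 in the 2-group fit, 0.280 with array weights, 0.223 without the 2 arrays, 0.279 without the 4 arrays, 0.102 without T1D low replicate 2 and 0.681 without AbN low replicate 3. The cell cycle list differed by −0.100 in the 2-group fit, −0.083 with probes detected on all 12 arrays, −0.061 with array weights, −0.054 without the 4 arrays, −0.076 with brightness, −0.143 without T1D low replicate 1 and −0.062 without AbN low replicate 2. Both had an adjusted p of 0.941 with the estimated correlation and 0.994 with fry. The type I interferon difference between the classes was 0.039 with array weights, 0.265 without the 4 arrays, −0.875 without AbN low replicate 1 and 0.125 without AbN low replicate 2.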

Other observations

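The tests of explanations and the counts of other splits in this part were chosen after the results were seen. Other splits of the arrays, 100 for a contrast over both strata with the real one included, gave as many genes at an unadjusted p under 0.05 as high against low sera in 6, so chance is not excluded. The real count was 1186 and the highest other 2322. For the lists called, 33 of 100 splits gave as many as the real 10, with 17 as the highest other, so chance is not excluded there either. For T1D against AbN sera the counts were 75 of 100 splits for genes (real 220, highest other 2532) and 93 for lists (real 2, highest other 17). For the difference between the classes they were 98 for genes (real 138, highest other 2219) and 89 for lists (real 3, highest other 17). Chance is not excluded for any of these. Splits with several times the real count, as in the latter 2 contrasts, may point to a structure of the samples, but none was tested. The highest split for high against low sera put 2 of the 4 arrays of lower neutrophil signal on each side, with both arrays of low hemoglobin signal on 1 side.

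Within a class, 10 splits are too few for a share under 0.05. Within AbN sera 3 of 10 gave as many genes (real 663, highest other 1293) and 8 as many lists (real 4, highest other 18). Within T1D sera 4 gave as many genes (real 631, highest other 1000) and 4 as many lists (real 8, highest other 10).

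Interferon lists were lower with high IL-1ra sera. The type I list differed by −1.143 ± 0.387 (SE) over all arrays. With array brightness as a covariate it differed by −1.030 ± 0.539, so brightness, which was on average higher with low IL-1ra sera, and serum group cannot be told apart here because the covariate widens the error. Within the 8 arrays of higher neutrophil signal it differed by −1.558 ± 0.333, and within the other 4 by −0.313. As these 4 lie 1 in each group, a shift common to them cancels in high minus low. The loss of hemoglobin signal was not common to them. HBB read 8.40 and 8.26 on the low IL-1ra arrays of the 4, and 13.84 and 14.28 on the high ones. The difference within the 4 carries this imbalance, and so does the difference over all arrays. Without the 2 arrays of low hemoglobin signal the type I list differed by −1.528. One of them is AbN low replicate 2, whose low type I score makes this fit favour a larger difference. These values do not decide whether the 4 arrays responded differently from the 8, and the labels name no batch. The monocyte list differed by −0.199 ± 0.095, less than the type I list. This argues against fewer monocytes as the cause only if interferon genes fall in step with monocyte markers, which was not tested. Different IL-1ra levels of the sera, and other components of the sera, stay open and were not tested.

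IL-1 and NF-kB genes were higher with high IL-1ra sera, by 0.496 ± 0.192. Without AbN high replicate 1, the array of highest score, the list differed by 0.343 ± 0.131, which argues against that 1 array as the whole cause. Within the 8 arrays of higher neutrophil signal it differed by 0.662 ± 0.197 and within the other 4 by 0.166. Whether the 4 arrays responded differently from the 8 stays undecided, for the same reasons as in the interferon lists. With array brightness as a covariate it differed by 0.457. The IL-1ra level of the sera stays open and was not tested. As chance is not excluded for the number of lists called, both patterns are hypotheses.

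Of the 29 lists not called for high against low sera, several had members past the threshold adjusted over the list alone, against 0 over all genes. In dendritic cell markers 5 were lower, in the monocyte list 1 was higher and 4 lower, in chemokines 5 were higher and 3 lower, and in anti-inflammatory monocyte genes 3 were lower. The chemokine list shares 8 genes with the IL-1 and NF-kB list and 2 with the interferon-gamma list, so these lists are not separate. The interferon-gamma list also shares 2 genes with the MHC class I list and 1 with the MHC class II list. CCL8 differed by −3.16 ± 0.66, MNDA by −0.97 ± 0.19 and CD1B by −0.89 ± 0.23.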
